A study of Homo sapiens with 12 samples.

How the data were processed

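Total RNA of K562 cells, an established human line from chronic myelogenous leukemia with erythroid features, was measured on 12 arrays. The cells had been grown in RPMI medium with 10% serum and 2 mM glutamine and treated for 20 hours, per the labels. The 3 groups of 4 arrays were vehicle (0.1% DMSO), mesoporphyrin at 20 uM, and iron mesoporphyrin at 20 uM. A DMSO percentage was recorded here for the vehicle arrays alone, so an equal amount of solvent in the compound groups is not known. Mesoporphyrin is a porphyrin, and iron mesoporphyrin is the same ring with a chelated Fe(III), per the labels. The 2 compounds were therefore compared at 1 dose and 1 time point. Samples carry preparation numbers from 1 to 4 in each group, and no label says whether these are separate cultures. The p-values below therefore measure only the spread between these samples, which may be technical.

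The authors deposited 1 table of log2 signals for 54675 probe sets on the 12 arrays. Values ran from 2.18 to 15.04, and array medians from 4.80 to 4.94. How the probe signals were summarised and normalized is not given in the sources used here. The platform annotation is that of a U133 Plus 2.0 array, whose probe sets lie mostly near the 3' ends of transcripts. The labels name biotin and a labelling kit for whole-transcript targets, and how the kit was used with this array is not given in the sources used here. The test had been planned for whole-transcript arrays, and nothing in it had to change. The values were used as deposited, with no further normalization and no filter on dim probe sets.

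Of the probe sets, 41097 (75.2%) had 1 gene symbol in the annotation, 1801 had several and 11777 had none, among which 62 were control probe sets. Symbols were updated through Entrez identifiers in a RefSeq gene table of GRCh38.p14, which matched 41043 of the 41097 and left 54 with their older symbol. No genome sequence was used, and no coordinates are given. Probe sets with several symbols were left out, and as a result both alpha-globin genes, both gamma-globin genes, HSPA1A, HSPA1B, FTH1 and GYPA were not analysed here. Each of the 19775 remaining genes was represented by the probe set with the highest mean over all arrays, and 10523 genes had several. For 1209 genes this was a probe set with the suffix x_at, which marks probes shared with other transcripts.

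Group means were fitted on all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), so that the groups shared 1 estimate of the spread per gene, with 16.8 degrees of freedom of which 7.8 came from the prior. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison. A gene is called, or said to have risen, fallen or changed, where its adjusted p lay below 0.05. Errors of log2 fold changes are standard errors of the fit, errors of levels are standard deviations of 4 arrays, and intervals are 95% confidence intervals. The number of arrays, 4 per group, limits the precision.

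Gene lists were fixed together with the rule for named genes, and 33 lists with at least 3 measured genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The lists were the study genes, NRF2 and BACH1 targets, heme synthesis, heme transport, globins, erythroid transcription factors, red cell membrane proteins, iron handling, iron-sulfur cluster assembly, heat shock, ATF4 targets, endoplasmic reticulum chaperones, metallothioneins with zinc exporters, the aryl hydrocarbon receptor battery, hypoxia targets, angiogenic factors, cholesterol synthesis, cell cycle, ribosome biogenesis, proteasome, respiratory chain, autophagy and lysosome, NF-kB targets, interferon-stimulated genes, immediate early genes, p53 targets, markers of megakaryocytes, of monocytes and granulocytes, of lymphocytes and of stromal and epithelial cells, histone genes, small nucleolar RNAs, and ribosomal proteins. A list of transcripts of the mitochondrial genome had 0 measured genes. The red cell membrane list also held red cell enzymes such as PKLR and the transcription factor E2F2, and the globin list also held AHSP, a chaperone of alpha-globin. Of 99 list tests, 15 gave a median, a mean and a camera direction that differed in sign, and 1 of the 15, the angiogenic factors between the compounds, was called.

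Named genes were chosen by rule. The rule took the 10 largest rises and the 10 largest falls of each comparison among called genes whose 4 values in 1 group all lay on the same side of the 4 values in the other. It added PGF, KLF1 and HMOX1 in every comparison and up to 4 called members of each list by size of change. Uncharacterised loci and small RNA genes were not named among the largest changes.

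The overlap of the comparisons with vehicle was set beside unchanged groups simulated against the same vehicle arrays in 100 draws, beside the overlap of independent lists, and beside splits of the 4 vehicle arrays. Control probe sets were compared between groups with two-sided exact permutation tests, which cannot give a p below 0.0286 with 4 against 4 arrays. The fits were tested on simulated data with known changes among 19775 genes. For iron mesoporphyrin against mesoporphyrin they recovered 47 of 67 genes changed by 0.5 on the log2 scale, 67 of 67 changed by 1 and 66 of 66 changed by 2, with 16 calls among 19545 unchanged genes. For iron mesoporphyrin against vehicle the numbers were 48, 65 and 66, with 14 such calls, and for mesoporphyrin against vehicle 56, 67 and 66, with 21. These simulations drew the errors of each gene separately, which leaves out spread that genes share on an array. False calls on the real arrays may therefore be more. Among the 100 draws of unchanged groups, which kept whole arrays together, up to 294 genes were called lower for mesoporphyrin.

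The groups, main tests, gene lists and naming rule were fixed before the data were examined. So were the alternatives, apart from 4 chosen after seeing the data. The test of non-coding genes against matched genes and that of probe sets against the GAPDH signal were also set after seeing the data. The alternatives fixed beforehand were the preparation number as a block, fits of 2 groups only, quantile normalization, median centring, a floor, a filter on dim genes, the mean of a gene's probe sets, every probe set tested, other moderation of the variance, no moderation, stricter thresholds, array weights, other set tests, and leaving out each array in turn. The 4 later ones were the brightest probe set without the x_at suffix, the GAPDH 5' minus 3' signal as a covariate, the poly-A spike-in signal as a covariate, and leaving out the 3 arrays with the highest hybridisation control signal. Figures were drawn with matplotlib 3.10.9.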

Results

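Transcript levels were measured on 12 arrays in K562 cells, a human leukemia line with erythroid features that makes hemoglobin under some inducers. The 3 groups of 4 arrays were cells given vehicle, mesoporphyrin or iron mesoporphyrin for 20 hours. Both compounds were given at 20 uM and differ by the chelated iron. A difference between them can come from a response to either compound. Against vehicle 5294 genes were called with mesoporphyrin and 3714 with iron mesoporphyrin, so their comparison does not isolate a response to iron. The series concerns placental growth factor (PGF), a relative of vascular endothelial growth factor, and the erythroid transcription factor KLF1. Signals of 19775 genes were compared, and with 4 arrays per group the number of arrays limits the precision. Correlations across genes, which are not independent replicates, were 0.9915 to 0.9974 for the 18 pairs of arrays within groups and 0.9788 to 0.9919 for the 48 pairs between groups. The first principal component, with 48.5% of the variance, set the mesoporphyrin arrays apart from the other groups, and the next, with 22.5%, set the vehicle arrays apart.

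Iron mesoporphyrin against mesoporphyrin was the comparison named in the study design. KLF1, which activates globin and other red cell genes, was 7.30-fold higher with iron mesoporphyrin than with mesoporphyrin (log2 difference 2.87 ± 0.10 SE, adjusted p = 1.57e-12). Its level was 9.70 ± 0.11 (SD, n = 4) on the log2 scale with vehicle, 7.02 ± 0.22 with mesoporphyrin and 9.89 ± 0.05 with iron mesoporphyrin. The larger departure from vehicle was on the mesoporphyrin arrays, where KLF1 fell 6.39-fold against vehicle (log2 change -2.68, adjusted p = 4.42e-12). With iron mesoporphyrin KLF1 differed from vehicle by 0.19 (95% interval -0.02 to 0.40, adjusted p = 0.208).

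PGF gave different results on its 2 probe sets. The brighter, with the suffix x_at, represents the gene by the rule used here and shares probes with other transcripts. It read 8.83 ± 0.29 (SD, n = 4) with vehicle, 8.81 ± 0.15 with mesoporphyrin and 8.91 ± 0.11 with iron mesoporphyrin, and the difference between the compounds was 0.11 (adjusted p = 0.543). Against vehicle it differed by 0.08 with iron mesoporphyrin (adjusted p = 0.696) and by -0.03 with mesoporphyrin (adjusted p = 0.916). The dimmer probe set, with the suffix s_at, lay at the 47.6th percentile of signal. It read 4.49 ± 0.08 with vehicle, 4.43 ± 0.22 with mesoporphyrin and 5.25 ± 0.24 with iron mesoporphyrin. On it PGF was 1.76-fold higher with iron mesoporphyrin than with mesoporphyrin (log2 difference 0.82, adjusted p = 4.79e-05) and 1.69-fold higher than with vehicle (0.76, adjusted p = 0.000249), while mesoporphyrin differed from vehicle by -0.06 (adjusted p = 0.813). Between the compounds this difference of 0.82 ± 0.12 (SE) became 0.70 ± 0.22 with the GAPDH 5' minus 3' signal as a covariate (adjusted p = 0.063) and 0.64 ± 0.21 with the poly-A spike-in signal (adjusted p = 0.0811). On the dimmer probe set the difference kept most of its size while its error widened. On the brighter one the difference of 0.11 between the compounds turned to -0.41 ± 0.165 (SE) with the GAPDH signal (adjusted p = 0.158). With the spike-in signal it was 0.02 ± 0.22 (adjusted p = 0.979). HMOX1, which encodes the inducible heme oxygenase, read 4.30 ± 0.22 with vehicle, 4.76 ± 0.10 with mesoporphyrin and 4.89 ± 0.07 with iron mesoporphyrin, near the 46.3rd percentile of signal. It rose 1.52-fold with iron mesoporphyrin (adjusted p = 0.000268) and 1.38-fold with mesoporphyrin (adjusted p = 0.00145), and the compounds differed by 0.14 (adjusted p = 0.318). The vehicle and mesoporphyrin levels of HMOX1, like those of the dimmer PGF probe set, lay below the array median of 4.87. These folds are therefore approximate. The change of HMOX1 with mesoporphyrin, 0.46 ± 0.10 (SE), became 0.30 ± 0.13 with the GAPDH signal as a covariate (adjusted p = 0.123). Of these 3 study genes 1 was called higher between the compounds, and camera gave an adjusted p of 0.0652, which became 0.049 without mesoporphyrin 2.

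**Figure D1:**
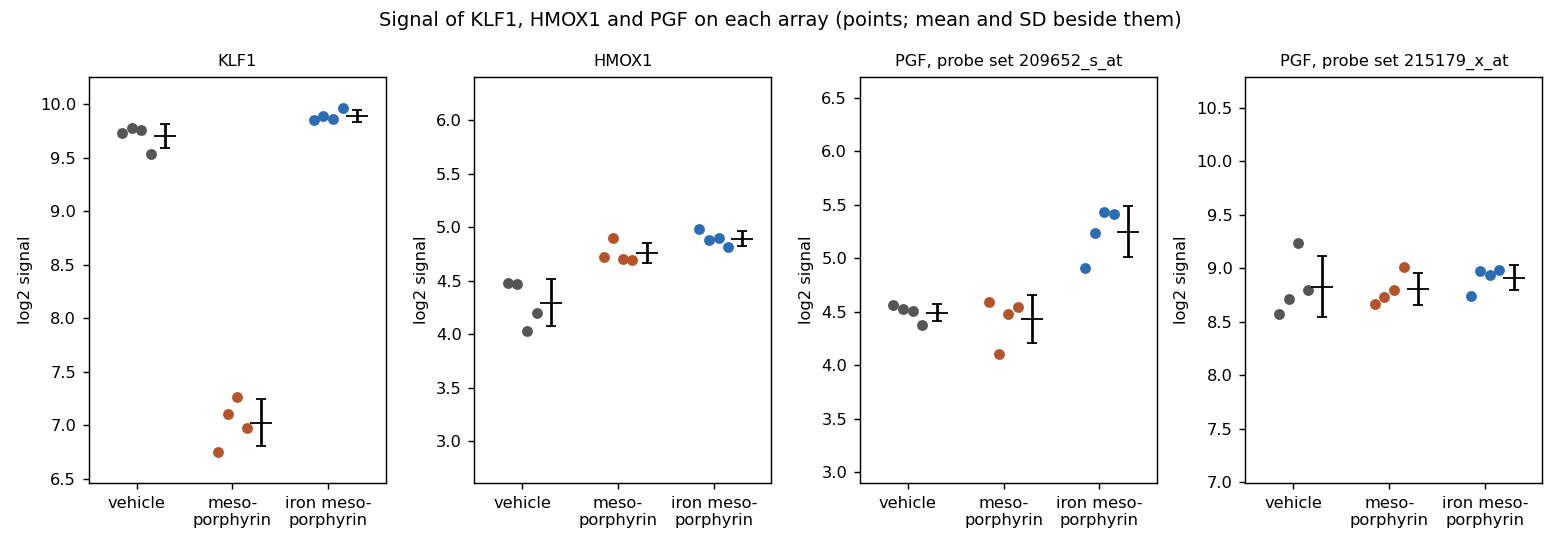
Log2 signal of the study genes on each array, with array values as points and group means with standard deviations for vehicle, mesoporphyrin and iron mesoporphyrin (4 arrays each). KLF1 was lower on the 4 mesoporphyrin arrays, and the probe sets of PGF differed in their response.

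Signals of single genes differed by up to 14.5-fold between the compounds. Among the 10 largest rises with iron mesoporphyrin relative to mesoporphyrin were TUBB1, a tubulin of platelets (10.3-fold, log2 difference 3.37 ± 0.13), C17orf99 (9.53-fold), KLF1, CAVIN2, a protein of caveolae (4.61-fold), TFR2, a sensor of transferrin (4.31-fold, log2 difference 2.11 ± 0.08), the aquaporin AQP10 (4.31-fold) and the chaperone DNAJB1 (4.30-fold). The others were C19orf84 and the long non-coding RNAs ZNF436-AS1 and MOCS2-DT, between 4.14-fold and 6.93-fold. Among the 10 largest falls were the transcription factors RUNX2 (14.5-fold, log2 difference -3.85 ± 0.12) and HEY1 (9.16-fold), the chemokines CXCL8 (7.97-fold, adjusted p = 1.68e-12) and CCL2 (7.79-fold), PHLDA1 (8.91-fold), the DNA sensor IFI16 (7.80-fold) and the protease inhibitor CSTA (6.82-fold). HECW2, ARG2 and RUSC1-AS1 completed the falls, and log2 differences of ARG2 varied between its probe sets. The dimmer group read 3.94 for TUBB1, 3.97 for RUNX2, 3.72 for CCL2 and 4.47 for MOCS2-DT, below the array median of 4.87 (mean of 12 arrays), so it was not shown to lie above background, and the folds and ranks of these genes are approximate. By the rule of choice the 4 values of a group lay apart from the 4 of the other in each of these largest changes. This held in 6526 of all 19775 genes. In total 3428 genes were called higher and 2958 lower with iron mesoporphyrin, or 32.3% of the 19775, against 8033 at an unadjusted p under 0.05.

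Many red cell genes were higher with iron mesoporphyrin than with mesoporphyrin. Of 26 measured genes of the red cell membrane list, which also holds red cell enzymes and the transcription factor E2F2, 17 rose and 1 fell. The counts were 18 and 1 adjusted over the list alone (camera adjusted p = 1.13e-07). The rises included PKLR, the red cell pyruvate kinase (2.94-fold), and the blood group genes ICAM4 (log2 difference 1.33) and ERMAP (1.22), with EPB42 (1.22). Of 14 heme synthesis genes 12 rose and 1 fell (the same counts adjusted over the list alone; adjusted p = 2.29e-06), among them UROS (3.23-fold, adjusted p = 3.46e-10) and PPOX (3.03-fold). Erythroid transcription factors rose in 11 and fell in 4 of 22 cases (12 and 4 adjusted over the list alone; camera adjusted p = 0.00193, and adjusted p = 0.165 with an estimated correlation). NFE2 (2.80-fold), IKZF1 (2.66-fold) and LDB1 (log2 difference 1.21) were among the rises beside KLF1. Of 7 measured genes of the globin list, which includes the alpha-globin chaperone AHSP, 2 rose and 0 fell by limma. The rises were AHSP (0.98) and HBD (0.75), and the counts were the same adjusted over the list alone. Camera did not call the globins (adjusted p = 0.0699), except without mesoporphyrin 2 (adjusted p = 0.0449). Among 24 iron handling genes 8 rose and 6 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.777). The iron exporter SLC40A1 rose (log2 difference 1.10), and EPAS1, the hypoxia-inducible factor with an iron-responsive element, fell (-2.15, 4.42-fold).

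Chaperones also set the compounds apart. Of 20 heat shock genes 17 rose and 1 fell with iron mesoporphyrin relative to mesoporphyrin (same counts adjusted over the list alone; adjusted p = 6.12e-11), with DNAJB4 (3.89-fold) and HSPH1 (3.39-fold) after DNAJB1. ATF4 targets, which respond to amino acid and other stresses, went the other way. Of 34 genes 24 fell and 2 rose (27 and 3 adjusted over the list alone; adjusted p = 3.28e-14), including ATF3 (3.58-fold lower), TRIB3 (log2 difference -1.38), CTH (-1.37) and DDIT4 (-1.28). Endoplasmic reticulum chaperones fell in 14 and rose in 2 of 21 genes (same counts adjusted over the list alone; adjusted p = 1.19e-07, and adjusted p = 0.0721 with an estimated correlation). HSPA5, the main chaperone of that compartment, fell 4.02-fold, although its second probe set moved the other way, from 8.33 with mesoporphyrin to 8.84 with iron mesoporphyrin. EDEM1 (-1.10) and HERPUD1 (-1.05) also fell. With the GAPDH 5' minus 3' signal as a covariate 9 of these 21 genes fell and 0 rose by limma, and the list median went from -0.60 to -0.38. The genes called lower went from a median of -0.86 to -0.65, and the median SE from 0.085 to 0.146.

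Cholesterol synthesis genes were lower with iron mesoporphyrin than with mesoporphyrin. Of 19 genes 14 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 1.34e-11), with SQLE 2.78-fold lower and ACAT2, MSMO1 and FDPS lower by log2 differences of -1.43, -1.42 and -1.39. NF-kB targets fell in 9 and rose in 1 of 20 genes (same counts adjusted over the list alone; adjusted p = 3.76e-05), with CXCL3 4.88-fold lower beside CXCL8 and CCL2. Immediate early genes fell in 14 and rose in 2 of 22 (same counts adjusted over the list alone, camera adjusted p = 1.13e-07). The falls included KLF6 (4.52-fold), KLF4 (log2 difference -1.95) and the kinase SGK1 (-1.86). With the GAPDH 5' minus 3' signal as a covariate 8 fell and 0 rose by limma, and the list median went from -0.46 to -0.30. The genes called lower did not shrink (medians -0.65 and -0.69), and the median SE went from 0.096 to 0.166. NRF2 and BACH1 targets went both ways, 5 up and 10 down of 28 (7 and 10 adjusted over the list alone), and camera did not call them (adjusted p = 0.0893). NQO2 (-1.16) and GCLC (-0.89), an enzyme of glutathione synthesis, were lower. Hypoxia targets rose in 9 and fell in 11 of 35 genes, with the same counts adjusted over the list alone, and the median of 0.03 and mean of 0.00145 lay opposite in sign to the direction of camera (adjusted p = 0.625). Metallothioneins and zinc exporters rose in 6 and fell in 0 of 11 genes by limma (8 and 1 adjusted over the list alone), including SLC30A10 (0.68) and SLC30A1 (0.40). Their camera call (adjusted p = 0.03) was lost without mesoporphyrin 1 (adjusted p = 0.0583), and adjusted p = 0.306 with an estimated correlation. With the GAPDH 5' minus 3' signal as a covariate 2 of the 11 rose and 0 fell by limma, the list median went from 0.31 to 0.015 and the median of the genes called higher from 0.38 to 0.11, while the median SE went from 0.098 to 0.174. With the same covariate 2 NRF2 and BACH1 targets rose and 3 fell, and 6 and 3 hypoxia targets. The genes called higher did not shrink (medians 0.34 to 0.44 and 0.56 to 0.76), those called lower did (-0.58 to -0.25 and -0.48 to -0.32), and the median SE went from 0.083 to 0.145 and from 0.085 to 0.15.

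Controls for RNA and labelling differed between the compounds, as did several lists of housekeeping genes. The GAPDH 5' minus 3' signal, a measure of how far labelled cDNA extends from the 3' end, was -4.52 ± 0.21 (SD, n = 4) with iron mesoporphyrin, -3.33 ± 0.34 with mesoporphyrin and -4.11 ± 0.49 with vehicle. Single arrays ran from -4.78 (iron mesoporphyrin 4) to -2.93 (mesoporphyrin 1). For ACTB they ran from -5.66 (iron mesoporphyrin 2) to -4.08 (vehicle 1). The 3' signal of these genes thus lay far above the 5' signal on every array, vehicle included, and the reason was not tested. The poly-A spike-in controls, added in a fixed amount, differed by -0.77 between iron mesoporphyrin and mesoporphyrin, and the 28S ribosomal RNA signal by -0.57. The ACTB 5' minus 3' signal differed by -0.20, in the direction of GAPDH but by far less. Each of these differences had the smallest p that an exact permutation test of 4 against 4 can give (p = 0.0286), and none passed after adjustment over the 18 tests of controls (adjusted p = 0.129). In the same comparison ribosome biogenesis genes fell in 10 and rose in 2 of 21 cases (11 and 2 adjusted over the list alone; camera adjusted p = 0.000925), with POLR1A, a subunit of RNA polymerase I, higher (0.77) and NOP16 lower (-0.79 ± 0.12, and -0.24 ± 0.15 with the GAPDH signal as a covariate, adjusted p = 0.38). Ribosomal protein genes fell in 19 and rose in 1 of 58 (same counts adjusted over the list alone; adjusted p = 3.65e-05, and adjusted p = 0.0916 with an estimated correlation). Respiratory chain genes fell in 15 and rose in 4 of 31 (16 and 6 adjusted over the list alone; adjusted p = 0.00262, and adjusted p = 0.204 with an estimated correlation). Iron-sulfur cluster assembly genes fell in 10 and rose in 3 of 19 (11 and 3 adjusted over the list alone; adjusted p = 0.00657, and adjusted p = 0.165 with an estimated correlation), with the scaffold ISCU lower by a log2 difference of -0.54. With the GAPDH 5' minus 3' signal as a covariate, the falls in these 4 lists came to 2, 2, 1 and 1 genes. Medians over whole lists stayed near their values for ribosome biogenesis (-0.22 and -0.17 with the covariate) and ribosomal proteins (-0.099 and -0.091), and were smaller for the respiratory chain (-0.21 and -0.043) and iron-sulfur cluster assembly (-0.21 and -0.045). The genes called lower had medians of -0.52, -0.70, -0.48 and -0.45, which became -0.22, -0.25, -0.17 and -0.11, while the median SE per list rose from between 0.071 and 0.088 to between 0.126 and 0.155.

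Proteasome genes fell in 10 and rose in 4 of 27 (10 and 5 adjusted over the list alone; camera adjusted p = 0.046, and adjusted p = 0.672 with an estimated correlation) between the compounds, with a median of -0.09 that turned to 0.08 under quantile normalization. With the GAPDH signal as a covariate 1 rose and 0 fell by limma, the median came to 0.21 and that of the genes called lower went from -0.62 to -0.05, so the falls were not seen apart from that signal. That call was lost without iron mesoporphyrin 4 (adjusted p = 0.135), mesoporphyrin 1 (0.0803), mesoporphyrin 2 (0.055) or mesoporphyrin 3 (0.0662). With an estimated correlation, 8 of the 16 list calls held in this comparison: red cell membrane, heme synthesis, heat shock, ATF4 targets, cholesterol synthesis, ribosome biogenesis, NF-kB targets and immediate early genes. The number of genes called between the compounds came to 1409 higher and 831 lower with the GAPDH 5' minus 3' signal as a covariate and to 1214 and 999 with the spike-in signal. The called genes' median size of 0.44 became 0.36 and 0.41 with these covariates, and the median SE of all genes rose from 0.094 to 0.162 and 0.164. The share of calls that were higher, 53.7%, became 40.9% (2430 higher and 3505 lower) when each array was centred on its median.

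**Figure D2:**
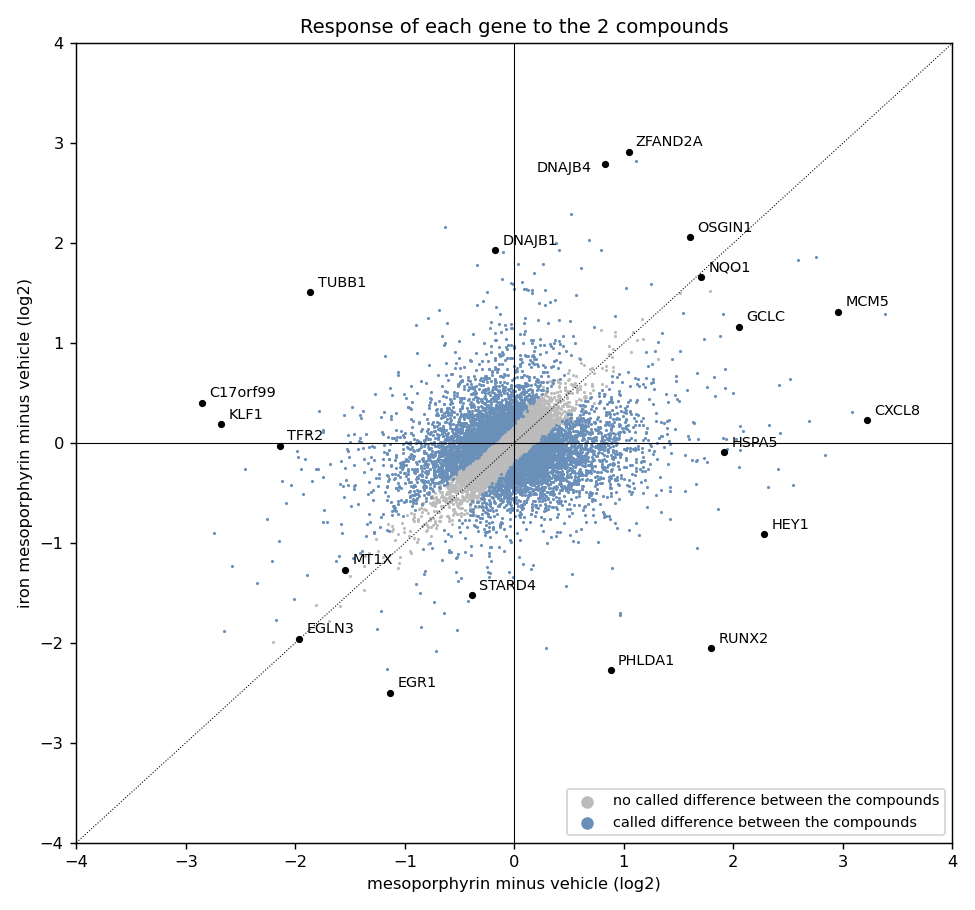
Each point is a gene, with the log2 difference of mesoporphyrin from vehicle on the horizontal axis and of iron mesoporphyrin from vehicle on the vertical axis (4 arrays per group). Blue points differed between the compounds by limma and grey points did not; KLF1 lay low on the horizontal axis and near 0 on the vertical one.

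Iron mesoporphyrin against vehicle showed what the iron-bearing compound did relative to the control. The largest rises included heat shock genes and an NRF2 target, and the largest falls included an immediate early gene and a hypoxia target. ZFAND2A, a heat- and arsenite-inducible protein, rose 7.55-fold (log2 change 2.92 ± 0.08, adjusted p = 2.36e-13), DNAJB4 6.91-fold, OSGIN1, a target of NRF2, 4.17-fold (adjusted p = 2.95e-11) and DNAJB1 3.81-fold. EGR1, an immediate early transcription factor, fell 5.66-fold (log2 change -2.50 ± 0.13, adjusted p = 3.88e-10). EGLN3, a prolyl hydroxylase of the hypoxia response, fell 3.88-fold (adjusted p = 1.85e-09).

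The other large rises were the pseudogene NMRAL2P (7.08-fold), the non-coding RNAs LINC00115 (4.90-fold) and ZNF436-AS1 (4.47-fold), TEX19 (log2 change 2.03), DYNLT2 (4.01-fold) and the matrix protein BCAN (3.81-fold). The other large falls were PHLDA1 (4.84-fold), ID3 (4.78-fold), BHLHE40 (4.23-fold), RUNX2 (4.16-fold), the metalloproteinase inhibitor TIMP1 (4.14-fold), EGFL7 (log2 change -1.99), COL1A2 (-1.87) and RNF183 (-1.87). The dimmer groups of NMRAL2P and RUNX2 lay below the array median, so these folds are approximate. By the same rule the groups did not overlap in these largest changes, as in 4707 of all 19775 genes. In total 1502 genes were called higher and 2212 lower (18.8%), against 5971 at an unadjusted p under 0.05.

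Heat shock genes rose in 18 and fell in 1 of 20 cases with iron mesoporphyrin (same counts adjusted over the list alone; camera adjusted p = 5.73e-20), including HSPA1L (log2 change 1.70) and HSPH1 (1.65). NRF2 and BACH1 targets rose in 19 and fell in 0 of 28 by limma (19 and 1 adjusted over the list alone; adjusted p = 3.47e-19). NQO1, a quinone reductase, rose 3.16-fold, the cystine transporter SLC7A11 3.01-fold and GCLM by 1.29 on the log2 scale. ATF4 targets rose in 13 and fell in 2 of 34 (15 and 2 adjusted over the list alone; adjusted p = 6.16e-05), with CHAC1 (1.07) and SESN2 (0.92). Endoplasmic reticulum chaperones rose in 6 and fell in 1 of 21 (7 and 1 adjusted over the list alone; adjusted p = 0.0371, and adjusted p = 0.372 with an estimated correlation), with HERPUD1 higher (0.44) and the sensor ATF6 lower (-0.93). This call was lost without vehicle 3 (adjusted p = 0.0692), iron mesoporphyrin 1 (0.0579) or iron mesoporphyrin 2 (0.0897).

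Cholesterol synthesis genes fell in 15 and rose in 0 of 19 cases against vehicle by limma (16 and 0 adjusted over the list alone; camera adjusted p = 3.47e-19). The sterol carrier STARD4 fell 2.87-fold (adjusted p = 1.86e-07), INSIG1 2.66-fold and MSMO1 by 1.26 on the log2 scale. Hypoxia targets fell in 21 and rose in 2 of 35 (23 and 2 adjusted over the list alone; adjusted p = 1.3e-10), with the glucose transporter SLC2A3 (log2 change -1.33), the aldolase ALDOC (-1.30) and PFKFB4 (-0.98) beside EGLN3. Metallothioneins and zinc exporters fell in 7 and rose in 1 of 11 (7 and 2 adjusted over the list alone; adjusted p = 0.000188, and adjusted p = 0.143 with an estimated correlation), led by MT1X (2.41-fold, adjusted p = 1.52e-07) and MT2A (-1.10), both on probe sets with shared probes. Ribosome biogenesis genes fell in 12 and rose in 0 of 21 by limma (18 and 0 adjusted over the list alone; adjusted p = 3.88e-08), among them MYC (-0.84), its general activator, and NOP16 (-0.74). Immediate early genes fell in 7 and rose in 4 of 22 (9 and 4 adjusted over the list alone; adjusted p = 0.0432, and adjusted p = 0.143 with an estimated correlation), with EGR3 (-0.96) and IER2 (-0.77) lower. That call was lost without vehicle 1 (adjusted p = 0.056) or iron mesoporphyrin 4 (0.0579).

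Red cell genes moved in both directions against vehicle. Of the 7 genes of the globin list, AHSP included, 4 rose and 0 fell by limma (5 and 0 adjusted over the list alone). Camera gave an adjusted p of 0.000348, and of 0.0683 with an estimated correlation. The rises included HBD (log2 change 0.87), the embryonic HBZ (0.85) and HBE1 (0.38). Erythroid transcription factors fell in 9 and rose in 1 of 22 (same counts adjusted over the list alone; adjusted p = 0.0167, and adjusted p = 0.274 with an estimated correlation), with LMO2 (-0.91), GATA1 (-0.81) and MYB (-0.71) lower and MAFG (0.70) higher. Of 14 heme synthesis genes 6 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0741, and 0.0322 without iron mesoporphyrin 4), with FECH, which inserts iron into the porphyrin ring, higher (0.58) and CPOX lower (-0.81). Genes of the red cell membrane list rose in 7 and fell in 1 of 26, the same adjusted over the list alone (camera adjusted p = 0.243), with EPB42 higher (0.82). Iron handling genes rose in 2 and fell in 4 of 24 (3 and 4 adjusted over the list alone; adjusted p = 0.307), with EPAS1 (-1.25) and NCOA4 (-0.50), the receptor for ferritin breakdown, lower.

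Lists of basic cell functions differed in how many of their genes moved against vehicle, where 18.8% of all genes were called. Respiratory chain genes fell in 8 and rose in 0 of 31 by limma (9 and 0 adjusted over the list alone; camera adjusted p = 0.00483, and adjusted p = 0.222 with an estimated correlation), with CYC1 lower (-0.54). With the GAPDH signal as a covariate 2 of them fell and 0 rose by limma, the list median went from -0.11 to -0.07 and that of the genes called lower from -0.30 to -0.24, with a median SE of 0.085 and 0.086. Iron-sulfur cluster assembly genes fell in 4 and rose in 0 of 19 by limma, also adjusted over the list alone (adjusted p = 0.0443, and adjusted p = 0.279 with an estimated correlation), with CIAO1 (-0.55) and GLRX5 (-0.36) lower. The call was lost without vehicle 1 (adjusted p = 0.0884), vehicle 4 (0.0648), iron mesoporphyrin 3 (0.0534) or iron mesoporphyrin 4 (0.0682). Proteasome genes rose in 6 and fell in 0 of 27 by limma, the same adjusted over the list alone (adjusted p = 0.0167, and adjusted p = 0.521 with an estimated correlation), with PSMC6 (0.42) and PSMD14 (0.40) higher. Without vehicle 3 this call was lost (adjusted p = 0.18). NF-kB targets fell in 2 and rose in 0 of 20 by limma, also adjusted over the list alone (camera adjusted p = 0.31), with TNFAIP3 (-0.85) lower. Of 58 ribosomal protein genes 0 rose and 0 fell by limma, also adjusted over the list alone (camera adjusted p = 0.216). RPL29 differed by -0.40 (adjusted p = 0.11) and RPL19 by -0.22 (adjusted p = 0.169), and both passed the threshold without vehicle 3 (adjusted p = 0.0212 and 0.0386). With an estimated correlation 6 of the 17 list calls held in this comparison, those of NRF2 and BACH1 targets, heat shock, ATF4 targets, hypoxia targets, cholesterol synthesis and ribosome biogenesis. When each array was centred on its median the share of calls that were higher went from 40.4% to 29.4% (1110 higher and 2666 lower), and with quantile normalization it was 49.3% (1734 higher and 1782 lower).

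Mesoporphyrin against vehicle showed the response to the porphyrin without iron. Many erythroid genes fell, and many ATF4, NRF2 and NF-kB targets rose. CXCL8, a chemokine for neutrophils, rose 9.34-fold (log2 change 3.22 ± 0.10, adjusted p = 8.16e-13), TAC1, the precursor of substance P, 10.4-fold (3.38 ± 0.17, adjusted p = 2.05e-10) and MCM5, a subunit of the replicative helicase, 7.78-fold (adjusted p = 4.81e-13). KLF1 fell 6.39-fold, and TFR2 fell 4.40-fold (log2 change -2.14 ± 0.08, adjusted p = 5.86e-12).

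The other large rises were CSTA (8.47-fold), IFI16 (7.16-fold), the receptor IL20RB (6.76-fold), the growth factor IGF1 (6.46-fold), S100P (6.02-fold), CCL2 (5.82-fold) and the retinal dehydrogenase ALDH1A1 (5.71-fold). The other large falls were C17orf99 (7.21-fold), the corepressor CBFA2T3 (6.71-fold), the receptor KISS1R (5.99-fold), CAVIN2 (5.51-fold), NAV1 (5.11-fold), the aquaporin AQP3 (4.79-fold), EGFL7 (4.62-fold), the collagen receptor GP6 (4.52-fold) and MCAM (log2 change -2.21). The dimmer group of TAC1 (3.21), CCL2 (4.14) and NAV1 (4.64) lay below the array median, that of TAC1 also below the lower quartile of 3.57, so these folds are approximate. MCAM differed by only -0.03 on its brightest probe set without the suffix x_at (adjusted p = 0.896). The groups did not overlap in these largest changes, again by the rule of choice, as in 5114 of all 19775 genes. In total 2165 genes were called higher and 3129 lower (26.8%), against 6894 at an unadjusted p under 0.05.

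Genes of the red cell membrane list fell in 14 and rose in 0 of 26 cases with mesoporphyrin by limma (15 and 0 adjusted over the list alone, camera adjusted p = 6.47e-07). The enzyme gene PKLR (log2 change -1.47), ICAM4 (-1.39) and the glucose transporter SLC2A1 (-1.04) were lower. Erythroid transcription factors fell in 13 and rose in 3 of 22 (13 and 4 adjusted over the list alone; adjusted p = 5.39e-06, and adjusted p = 0.0652 with an estimated correlation), with NFE2 4.25-fold lower and IKZF1 (-1.75) and GFI1B (-1.46) also lower. Heme synthesis genes fell in 8 and rose in 1 of 14, also adjusted over the list alone (adjusted p = 0.000263, and adjusted p = 0.103 with an estimated correlation). CPOX fell 3.00-fold, UROS 2.65-fold and PPOX by 1.12 on the log2 scale. Genes of the globin list rose in 3 and fell in 1 of 7, with the same counts adjusted over the list alone (camera adjusted p = 0.238). The 1 fall was that of the chaperone AHSP (-0.85), so no measured globin was called lower. The alpha- and gamma-globin genes were not analysed here, so whether they fell is not known. With the GAPDH signal as a covariate 0 genes of this list rose and 1 fell by limma. The median of the genes called higher went from 0.46 to 0.22 and the median SE from 0.116 to 0.134. Of 24 iron handling genes 4 rose and 10 fell (5 and 10 adjusted over the list alone; adjusted p = 0.309), among them the ferrireductase STEAP3 (-1.06) and SLC40A1 (-0.94) beside TFR2.

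ATF4 targets rose in 29 and fell in 1 of 34 cases with mesoporphyrin, with the same counts adjusted over the list alone (camera adjusted p = 1.74e-25), led by ATF3 (5.35-fold, adjusted p = 3.33e-11), CTH (log2 change 1.93), CHAC1 (3.68-fold) and SESN2 (1.52). NRF2 and BACH1 targets rose in 22 and fell in 0 of 28 by limma (24 and 0 adjusted over the list alone; adjusted p = 1.29e-21), with GCLC (4.14-fold, adjusted p = 7.01e-12), GCLM (3.74-fold), NQO1 (3.27-fold) and OSGIN1 (3.05-fold). Endoplasmic reticulum chaperones rose in 15 and fell in 2 of 21 (16 and 3 adjusted over the list alone; adjusted p = 3.45e-10), with HSPA5 (3.77-fold), HERPUD1 (1.49) and MANF (1.29). Heat shock genes rose in 7 and fell in 2 of 20 (7 and 4 adjusted over the list alone) and were not called by camera (adjusted p = 0.31), with DNAJB4 higher (0.83) and DNAJA1 lower (-0.57). NF-kB targets rose in 8 and fell in 1 of 20, also adjusted over the list alone (adjusted p = 6.81e-05), and CXCL3 rose 4.14-fold. Immediate early genes rose in 11 and fell in 5 of 22, the same adjusted over the list alone (adjusted p = 0.00084), with KLF4 (1.76), IER3 (1.56) and SGK1 (1.42).

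Hypoxia targets fell in 20 and rose in 1 of 35 cases with mesoporphyrin (22 and 4 adjusted over the list alone; camera adjusted p = 5.39e-06), with PFKFB4 (4.44-fold), EGLN3 (3.91-fold) and SLC2A3 (log2 change -1.50). Metallothioneins and zinc exporters fell in 8 and rose in 1 of 11, also adjusted over the list alone (adjusted p = 7.18e-06, and adjusted p = 0.0731 with an estimated correlation), with MT1X 2.91-fold and MT2A 2.66-fold lower. Cholesterol synthesis genes rose in 4 and fell in 6 of 19 (5 and 7 adjusted over the list alone), with INSIG1 lower (-0.90), and their median of 0.02 and mean of -0.05 differed in sign (camera adjusted p = 0.942). Ribosome biogenesis genes rose in 2 and fell in 6 of 21 (2 and 7 adjusted over the list alone; adjusted p = 0.349), with POLR1A lower (-1.03). With the GAPDH signal as a covariate 0 rose and 3 fell by limma, the genes called lower going from a median of -0.37 to -0.28 and the median SE from 0.088 to 0.114. MYC went from -0.13 (limma adjusted p = 0.587) to -0.61 with this covariate (adjusted p = 0.00312). With iron mesoporphyrin against vehicle it was -0.60 with the covariate, so its fall was then alike with both compounds.

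The GAPDH 5' minus 3' signal was higher by 0.78 with mesoporphyrin than with vehicle, and the poly-A spike-in and 28S signals by 0.51 and 0.57 (p = 0.0571 each in exact permutation tests; adjusted p = 0.147). The ACTB 5' minus 3' signal differed by -0.22 (exact permutation p = 0.971), a sign that rested on vehicle 1. That array read -4.08 and the other vehicle arrays -5.61 to -5.44, against a mean of -5.38 with mesoporphyrin. Beside these, ribosomal protein genes rose in 16 and fell in 1 of 58 cases, also adjusted over the list alone (camera adjusted p = 0.000263, and adjusted p = 0.127 with an estimated correlation). Proteasome genes rose in 13 and fell in 0 of 27 by limma, the same adjusted over the list alone (adjusted p = 1.03e-05, and adjusted p = 0.376 with an estimated correlation). Respiratory chain genes rose in 7 and fell in 1 of 31, with the same counts adjusted over the list alone (adjusted p = 0.309), and iron-sulfur cluster assembly genes rose in 8 and fell in 5 of 19 (9 and 6 adjusted over the list alone; adjusted p = 0.309), with ISCU higher (0.74) and CIAO1 lower (-0.81). With the GAPDH signal as a covariate the rises in these 4 lists came to 5, 4, 0 and 3 genes. The median over all ribosomal protein genes stayed at 0.07 and that over proteasome genes went from 0.28 to 0.04, while the genes called higher went from medians of 0.52 and 0.50 to 0.24 and 0.22. With an estimated correlation 7 of the 13 list calls held in this comparison, those of NRF2 and BACH1 targets, red cell membrane, ATF4 targets, endoplasmic reticulum chaperones, hypoxia targets, NF-kB targets and immediate early genes. Against vehicle 1282 genes were called higher and 2384 lower with the GAPDH signal as a covariate, and 1224 and 2039 with the spike-in signal. The called genes' median size of 0.45 became 0.42 and 0.43, so it stayed close, while the median SE of all genes rose from 0.094 to 0.126 and 0.128.

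**Figure D3:**
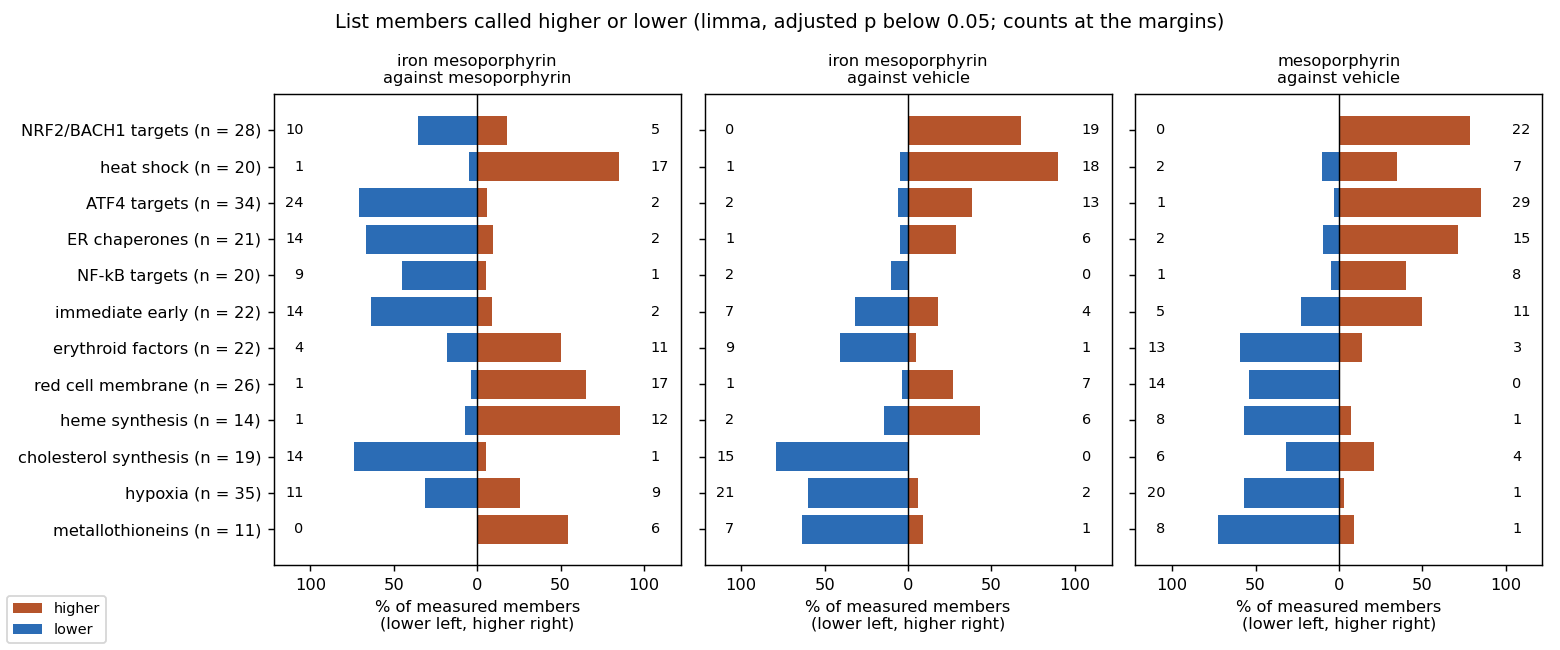
Percent of the measured genes of 12 lists called higher (to the right) or lower (to the left) by limma in the 3 comparisons, with the number of genes at the margins. Genes of the red cell membrane list, some of which encode enzymes, were mostly lower with mesoporphyrin than with vehicle, and higher with iron mesoporphyrin than with mesoporphyrin.

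Responses to the compounds were set side by side at the same dose and time. Relative to vehicle, 419 genes were called higher with both compounds, 1059 lower with both, and 486 in opposite directions, of which 231 were higher with iron mesoporphyrin and 255 with mesoporphyrin. Of the genes called the same way with both, 236 higher and 676 lower had no called difference between the compounds. NQO1 was such a gene, with a difference of -0.05 between iron mesoporphyrin and mesoporphyrin (95% interval -0.20 to 0.10), as were EGLN3 (0.01, interval -0.23 to 0.24), SLC2A3 (0.17, interval -0.04 to 0.39) and MT1X (0.27, interval 0.05 to 0.49, adjusted p = 0.0546). Dimmer probe sets of these genes were called between the compounds, with -1.08 and -0.86 for NQO1, 0.39 for EGLN3, -0.34 and -0.74 for SLC2A3 and 0.37 for MT1X. Other NRF2 targets differed, GCLM being lower with iron mesoporphyrin (log2 difference -0.61, adjusted p = 0.000103, with other probe sets at -0.28 and -0.44 short of the threshold) and OSGIN1 higher (0.45, adjusted p = 0.000253).

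A larger number of genes changed with mesoporphyrin relative to both other groups. Mesoporphyrin was higher than vehicle and than iron mesoporphyrin in 1637 genes and lower than both in 1883, and of these 1259 and 1367 were not called between iron mesoporphyrin and vehicle. For TFR2 the difference between iron mesoporphyrin and vehicle was -0.03 (95% interval -0.20 to 0.14), for HSPA5 -0.09 (-0.32 to 0.14) and for CXCL8 0.23 (0.01 to 0.45, adjusted p = 0.144). Other probe sets gave a rise of 1.20 for HSPA5 (adjusted p = 6.32e-07) and -0.26 for TFR2 (adjusted p = 0.0398), so these cases hold for the brightest probe set alone. Iron mesoporphyrin was higher than both other groups in 921 genes and lower in 1033, with ZFAND2A (log2 difference from mesoporphyrin 1.87) among the higher. Independent lists would have shared 164.4 higher and 350 lower genes, a value that leaves out the shared vehicle arrays. Simulated unchanged groups against the same vehicle arrays shared 0 in 100 draws, but they had on average only 0.06 genes higher and 0 lower for iron mesoporphyrin and 1.2 and 3.19 for mesoporphyrin by limma, so this 0 gives no measure of the overlap that shared arrays add. Across genes, which are not independent replicates, the log2 differences from vehicle of the compounds had a Pearson correlation of 0.263 and a Spearman correlation of 0.244, against a mean Pearson correlation of 0.481 for simulated unchanged groups. The covariance was 0.0252 against 0.00587 in the simulation, a difference of 0.0194. With the vehicle arrays split so that the comparisons shared none, 240 to 281 genes were higher and 585 to 720 lower with both compounds, and the correlation was 0.052 to 0.300 over 6 splits.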

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

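The tests of other splits of the arrays were planned, and the genes examined for single arrays that stood apart were the named genes with the largest changes. Among 168 groups of 4 arrays, for 50 genes and 6 control measures, 10 held an array whose gap to its nearest neighbour was large for the range of the group. Chance alone gives about 1 in 20 such groups, or 8.4 here, so the number of such arrays was close to that of chance. No biological explanation was tested for them.

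Values that stood apart are given as the array minus the mean of the other 3 arrays of its group, on the log2 scale. CCL2 was lower by -0.69 on mesoporphyrin 4 and by -0.66 on iron mesoporphyrin 4, and S100P by -0.50 on iron mesoporphyrin 4. MOCS2-DT lay -0.069 from the others on iron mesoporphyrin 4, and BCAN -0.20 on vehicle 4. CXCL8 was higher by 0.39 on vehicle 3. On mesoporphyrin 2, DNAJB1 differed by -0.16, HMOX1 by 0.19 and NMRAL2P by -0.39. The ACTB 5' minus 3' signal was higher by 1.44 on vehicle 1.

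No other assignment of the arrays to groups gave as many called genes as the real one. The other splits mix the group difference into the spread, which by itself lowers their counts. With 35 splits the share cannot fall below 0.0286, so the test cannot exclude chance. It does not address a technical difference between the groups either. Of the 35 splits of the 8 arrays of iron mesoporphyrin and mesoporphyrin into 4 and 4, 1 gave as many genes as the 6386 called, namely the real one, and the highest of the other splits gave 0 by limma and 3892 at an unadjusted p under 0.05. For iron mesoporphyrin and vehicle 1 of 35 splits gave as many as 3714, and the highest of the others gave 0 by limma and 2966 unadjusted. For mesoporphyrin and vehicle 1 of 35 gave as many as 5294, and the highest of the others gave 1.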

How the results depend on the processing

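The probe sets without the suffix x_at, both covariates and the set without 3 arrays were chosen after seeing the data. The other alternatives were planned. Each count below gives genes higher and lower for iron mesoporphyrin against mesoporphyrin, iron mesoporphyrin against vehicle and mesoporphyrin against vehicle, in that order. With every probe set tested, probe sets rather than genes were counted, 7052 and 6734, 3167 and 4129, and 5180 and 6115. A fold of at least 1.5 left 895 and 1132, 358 and 462, and 756 and 910, with 80 higher and 173 lower with both compounds, and a fold of at least 2 left 259 and 320, 105 and 89, and 223 and 225. An adjusted p below 0.01 left 891 and 1386 for iron mesoporphyrin against vehicle. With the GAPDH 5' minus 3' signal as a covariate the counts were 1409 and 831 between the compounds, and 1282 and 2384 for mesoporphyrin against vehicle. With the poly-A spike-in signal they were 1214 and 999 between the compounds and 1224 and 2039 for mesoporphyrin against vehicle. A covariate that differs between groups also widens the errors. The median SE of all genes was 0.094, and 0.162 and 0.164 with the covariates between the compounds, where 94.9% and 98.7% of the called genes kept their sign. For mesoporphyrin against vehicle it was 0.126 and 0.128, the called genes' median size went from 0.45 to 0.42 and 0.43, and 99.5% and 100% kept their sign. Without iron mesoporphyrin 4, mesoporphyrin 2 and mesoporphyrin 4, which had the highest hybridisation control signal, the counts were 2682 and 2507, 1452 and 1958, and 2047 and 2600.

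Leaving out each array in turn gave 2969 to 3844 genes higher and 2595 to 3098 lower between the compounds, 1200 to 1677 and 1725 to 2492 for iron mesoporphyrin against vehicle, and 1857 to 2284 and 2692 to 3158 for mesoporphyrin against vehicle. Genes called with both compounds ranged from 341 to 444 higher and from 829 to 1106 lower. With the preparation number as a block the counts were 3310 and 2880, 1446 and 2083, and 2105 and 2985, and 391 and 971 genes were called with both compounds. Deviations of equally numbered arrays correlated between -0.0617 and 0.312, between -0.236 and 0.0985, and between -0.215 and 0.0442 in the 3 comparisons. An array correlated best with its own number in 2, 1 and 0 of 4 cases, so the numbers gave no general sign of pairing. Number 4 stood out between the compounds, with a correlation of 0.312 and the highest hybridisation control signals of the 12 arrays (11.5 and 11.55). Vehicle 4 correlated with these arrays at -0.202 and -0.0829. Whether the number 4 arrays of the compounds shared a step of preparation was not tested. The block ended 4 of 385 calls of named genes and 2 of 46 list calls, those of immediate early genes and of stromal and epithelial markers for iron mesoporphyrin against vehicle.

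Several named genes changed direction, of which IDI1 alone passed the threshold in the new direction, and the cause was not tested. Between the compounds, with the GAPDH signal as a covariate, PRDX1 came to 0.016, PGD to 0.15, NR1D2 to 0.020, MT1H to -0.0082, MYC to 0.011 and IRF9 to 0.070, and ARNT came to 0.0066 with the spike-in signal. For iron mesoporphyrin against vehicle, MT1G came to 0.050 and IDI1 to 0.60 (adjusted p = 0.0315) on probe sets without the suffix x_at. ARNT came to 0.0043 with the mean of its probe sets. For mesoporphyrin against vehicle, HBB came to -0.0089 and CDT1 to 0.29 on probe sets without the suffix x_at, and HSP90AB1 to -0.018 with the GAPDH covariate. In the same comparison EBP, NOLC1 and COL1A2 came to 0.085, 0.014 and 0.031 with the mean of their probe sets.

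Of 385 calls of named genes, the GAPDH covariate ended 77, the spike-in covariate 69, the mean of probe sets 27, lack of moderation 25, quantile normalization 12, a floor 10 and median centring 7. Leaving out each array in turn ended such a call in 123 of 4752 refits of named genes, called or not. Of 46 list calls among 99 tests, an estimated correlation ended 25, and fry ended 2 and added 29. Over 17 settings the dimmer PGF probe set gave log2 differences of 0.64 to 0.93 between the compounds, past the threshold in 15, and of 0.70 to 0.87 against vehicle, past it in 17. The brighter PGF probe set passed it in 0 of 17 settings by limma in each comparison. Between the compounds it ran from -0.41, with the GAPDH covariate, to 0.19, so its sign depended on the setting. With the mean of both, PGF differed by 0.46 between the compounds (adjusted p = 0.00188). Dim signals limit what the arrays show of PGF and HMOX1, since background makes up more of a dim signal and narrows its fold changes.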

Other observations

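The share of non-coding genes that were higher was set against matched genes, and the probe sets of single genes were set against the GAPDH signal, only after these results were seen, and the GAPDH and spike-in covariates were added after seeing the data. Lists of lesser bearing on the study moved as follows. Autophagy and lysosome genes rose in 8 and fell in 10 of 26 between iron mesoporphyrin and mesoporphyrin (9 and 11 adjusted over the list alone; camera adjusted p = 0.296), with a median of 0.02 and a mean of -0.18. MAP1LC3B (log2 difference -2.07) and the lysosomal NEU1 (-1.64) were lower. With mesoporphyrin against vehicle 10 rose and 6 fell (10 and 8 adjusted over the list alone; adjusted p = 0.14), among them MAP1LC3B (1.66), and with iron mesoporphyrin 5 rose and 5 fell (5 and 6 adjusted over the list alone; adjusted p = 0.95), with SQSTM1 higher (1.11) and BNIP3L lower (-0.79). Of 36 cell cycle genes 8 rose and 8 fell between the compounds, also adjusted over the list alone (adjusted p = 0.573), 2 rose and 10 fell with iron mesoporphyrin (2 and 13 adjusted over the list alone; adjusted p = 0.0127, and adjusted p = 0.2 with an estimated correlation) and 5 rose and 15 fell with mesoporphyrin (5 and 16 adjusted over the list alone; adjusted p = 0.157). MCM5, a subunit of the replicative helicase, rose with both compounds, by 1.31 with iron mesoporphyrin and 2.96 with mesoporphyrin. Of 16 p53 targets and apoptosis genes, 2 rose and 5 fell between the compounds, 1 rose and 4 fell with iron mesoporphyrin, and 4 and 4 moved with mesoporphyrin (2 and 5, 1 and 4, and 5 and 5 adjusted over the list alone; adjusted p = 0.137, 0.789 and 0.428). PMAIP1 rose by 0.84 with iron mesoporphyrin and by 1.44 with mesoporphyrin, and the death receptor gene TNFRSF10B by 0.96 with mesoporphyrin.

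Angiogenic factors, the group that PGF belongs to, rose in 1 and fell in 6 of 22 cases between the compounds, also adjusted over the list alone (camera adjusted p = 0.0436, and adjusted p = 0.0916 with an estimated correlation). Their mean was -0.28, and their median of 0.0031 turned to -0.05 under quantile normalization and -0.06 under median centring. The call was lost without iron mesoporphyrin 1 (adjusted p = 0.0576) or mesoporphyrin 1 (0.0549). FGF2 (log2 difference -1.33), PDGFA (-1.11) and VEGFA (-0.95) were lower. Against vehicle 0 rose and 4 fell with iron mesoporphyrin by limma (0 and 6 adjusted over the list alone; adjusted p = 0.243), with PDGFA (-1.34) and VEGFA (-0.68), and 3 rose and 2 fell with mesoporphyrin, also adjusted over the list alone (adjusted p = 0.309), with FGF2 higher (0.88). Megakaryocyte markers rose in 4 and fell in 2 of 18 between the compounds, also adjusted over the list alone (adjusted p = 0.361), and TUBB1 rose by 1.51 with iron mesoporphyrin and fell by 1.86 with mesoporphyrin. Against vehicle 2 rose and 1 fell with iron mesoporphyrin (3 and 1 adjusted over the list alone; adjusted p = 0.586) and 2 rose and 4 fell with mesoporphyrin, the same adjusted over the list alone (adjusted p = 0.473). The aryl hydrocarbon receptor battery rose in 1 and fell in 3 of 12 between the compounds, in 2 and 2 with iron mesoporphyrin and in 2 and 0 with mesoporphyrin by limma, all the same adjusted over the list alone (adjusted p = 0.558, 0.475 and 0.309). Heme transport and breakdown genes rose in 5 and fell in 6 of 15 between the compounds (5 and 7 adjusted over the list alone; adjusted p = 0.625), in 3 and 2 with iron mesoporphyrin and in 3 and 4 with mesoporphyrin, both also adjusted over the list alone (adjusted p = 0.586 and 0.271). The heme transporter SLC48A1 rose by 0.84 and 0.60 with the compounds, and the heme exporter FLVCR1 fell by 0.73 with iron mesoporphyrin.

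Interferon-stimulated genes rose in 3 and fell in 2 of 20 between the compounds, in 2 and 0 with iron mesoporphyrin and in 3 and 0 with mesoporphyrin by limma, all the same adjusted over the list alone (camera adjusted p = 0.8, 0.0412 and 0.168). For iron mesoporphyrin against vehicle the call gave adjusted p = 0.147 with an estimated correlation and was lost without vehicle 3 (adjusted p = 0.101), and BST2 was higher (0.61). Histone genes rose in 12 and fell in 3 of 50 between the compounds, also adjusted over the list alone (adjusted p = 0.0788), with H2BC4 higher (1.75) after it fell by 1.91 with mesoporphyrin. They rose in 6 and fell in 2 with iron mesoporphyrin, the same adjusted over the list alone (adjusted p = 0.31), and rose in 1 and fell in 7 with mesoporphyrin (0 and 5 adjusted over the list alone; adjusted p = 0.326). Small nucleolar RNAs rose in 3 and fell in 2 of 16 between the compounds, in 2 and 0 with iron mesoporphyrin and in 4 and 0 with mesoporphyrin by limma, all the same adjusted over the list alone (adjusted p = 0.74, 0.0701 and 0.0826). Markers of monocytes and granulocytes rose in 1 and fell in 0 of 18 between the compounds (0 and 0 adjusted over the list alone; adjusted p = 0.777) and moved in 0 cases against vehicle by limma with either compound, also adjusted over the list alone (adjusted p = 0.628 and 0.982). CSF3R differed by 0.21 with iron mesoporphyrin (adjusted p = 0.146) and 0.20 with mesoporphyrin (adjusted p = 0.13). Lymphocyte markers rose in 2 and fell in 1 of 18 between the compounds (0 and 1 adjusted over the list alone; adjusted p = 0.593), in 1 and 1 with iron mesoporphyrin and in 0 and 1 with mesoporphyrin by limma, both also adjusted over the list alone (adjusted p = 0.586 and 0.595), with CD3D lower by -1.59 and -0.73. Stromal and epithelial markers rose in 2 and fell in 3 of 17 between the compounds, also adjusted over the list alone (adjusted p = 0.8). With iron mesoporphyrin 0 rose and 5 fell by limma (3 and 6 adjusted over the list alone; adjusted p = 0.0443, and adjusted p = 0.143 with an estimated correlation), a call lost without vehicle 3 (adjusted p = 0.058), iron mesoporphyrin 1 (0.0559) or iron mesoporphyrin 4 (0.0626). With mesoporphyrin 0 rose and 5 fell by limma, the same adjusted over the list alone (adjusted p = 0.0287, and adjusted p = 0.0926 with an estimated correlation), with PECAM1 (-2.12) and KRT19 (-1.38) lower.

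With the GAPDH 5' minus 3' signal as a covariate some of these counts between the compounds changed. Histone genes rose in 12 and fell in 0 cases by limma, the genes called higher going from a median of 0.57 to 0.81 and the 3 called lower turning from -0.68 to 0.47 (median SE 0.098 and 0.163). Heme transport and breakdown genes rose in 2 and fell in 0 by limma, with medians going from 0.35 to 0.24 and from -0.39 to -0.08 (median SE 0.094 and 0.16). Cell cycle genes rose in 2 and fell in 1, with medians of 0.37 both times and of -0.45 and -0.30 (median SE 0.089 and 0.147), and autophagy and lysosome genes rose in 3 and fell in 5, with medians of 0.40 and 0.41 and of -0.56 and -0.53 (median SE 0.086 and 0.149). The aryl hydrocarbon receptor battery, interferon-stimulated genes, lymphocyte markers and small nucleolar RNAs rose in 0, 1, 0 and 1 and fell in 0, 1, 1 and 1 cases, with median SEs of 0.164 to 0.18 against 0.095 to 0.104 without it. Their genes called higher went from medians of 0.27, 0.32, 0.31 and 0.36 to 0.23, 0.43, 0.083 and 0.16, and those called lower from -0.34, -0.40, -0.86 and -0.48 to -0.19, -0.24, -0.71 and -0.35. For mesoporphyrin against vehicle 2 heme transport genes rose and 1 fell (medians 0.46 to 0.53 and -0.32 to -0.24, median SE 0.094 and 0.124), and 1 interferon-stimulated gene rose (0.34 to 0.064, median SE 0.104 and 0.136).

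In 15 of 99 list tests the median, mean and camera direction differed in sign. Beside those named, they were heme transport, the aryl hydrocarbon receptor battery, cell cycle and small nucleolar RNAs between the compounds, angiogenic factors, autophagy, p53 targets and lymphocyte markers with iron mesoporphyrin, and the aryl hydrocarbon receptor battery, megakaryocyte and monocyte markers with mesoporphyrin.

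The fall of 35 erythroid and heme synthesis genes with mesoporphyrin (median log2 change -0.876, quartiles -1.38 and -0.54) stood beside a higher GAPDH 5' minus 3' signal and a higher spike-in signal on those arrays. With the GAPDH signal as a covariate the median was -0.864 and 32 of the 35 were still called lower, which argues against uneven cDNA length, as GAPDH measures it, as the whole cause. With the spike-in signal as a covariate it was -0.881 and 30 were still called. This argues against a lower amount of sample RNA, as the spike-ins measure it, as the whole cause. A response to the porphyrin itself remains a hypothesis that may account for the fall. The genes were chosen on these arrays as those called lower in 3 lists, which enlarges their median and favours that they stay called. Over all measured members the medians were -0.49 for erythroid factors, -0.35 for the red cell membrane list and -0.26 for heme synthesis, with 3, 0 and 1 called higher. With the GAPDH signal as a covariate these medians were -0.53, -0.28 and -0.36. With the spike-in signal medians over all members were not examined, so that result covers the chosen genes alone.

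Long non-coding genes that changed with iron mesoporphyrin were mostly higher than with vehicle, 273 higher and 43 lower of 2658 tested, or 86.4%. Protein-coding genes matched on mean signal gave 51.3% on average and at most 57.5% in 100 draws, and all protein-coding genes 35.2%, which argues against a shift of dim signals as the whole cause. With the GAPDH 5' minus 3' signal as a covariate the share was 84.6%, against 49.4% on average and at most 57.6% for matched genes, which argues against uneven cDNA length, as GAPDH measures it, as the whole cause. A change in the making or decay of such transcripts with the compound could give this and was not tested, nor was read-through from neighbouring genes.

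Probe sets of a single gene often disagreed between the compounds. Of 2420 genes with several bright probe sets, 289 had probe sets whose responses differed by more than 1 on the log2 scale. In YKT6 a pair of probe sets gave log2 differences of -2.32 and -0.08, and in the transferrin receptor gene TFRC -1.93 and -0.29. The smaller TFRC difference was on a probe set at the 99.7th percentile of signal, and an effect of signal level was not tested. In 87.5% of the 289 the gap followed the GAPDH 5' minus 3' signal within groups (0 of 100 shuffles gave as high a share, the highest being 86.9%), consistent with uneven cDNA length as GAPDH alone measures it, whose within-group slope gave a median of 34.9% of the gap. Shared probes, as the suffix x_at marks them, were argued against as the general cause, since 13.5% of these pairs held such a probe set against 20.5% of all. Probe sets with other suffixes were not counted. A real change in transcript ends or isoforms stays open for the rest.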
